A study of Pimephales promelas with 12 samples.

How the data were processed

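RNA from whole larvae of 12 beakers (control, 24.5 and 47.8 mg/L IMX-104, 4 each) was hybridised to one-colour Agilent arrays, 1 array per beaker, starting from 200 ng of total RNA per the labels' protocols. Replicates were separate beakers of the same exposure, per the labels. Scanned images were quantified with Agilent Feature Extraction 10.7.3.1, per the file headers; the submitters' processing notes also name that program. The deposited scanner files give each spot's intensity: the processed signal is background-subtracted and detrended within the array, and the median signal and median local background are raw brightness, per the file headers. No between-array normalization is recorded in these headers. The authors' deposited value table holds log2 values. Set against the scanner values it matched log2 processed signal, shifted by each array's 75th percentile and centred on each probe's median (r at least 0.9999 per array, SD of the difference at most 0.00647). Its column medians ranged from -0.11 to 0.35, and its scale, centring and direction were settled by that comparison.

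The 1319 control-type spots were left out, which left 61053 spots of 49849 probes: 41517 probes with 1 spot, 7973 with 2 and 359 with 10. Spots with an outlier flag were removed, and no spot was saturated. The log2 processed signal was scaled by subtracting each array's 75th percentile over all probes, and spots of a probe were averaged. A probe was kept when well above background on at least 4 of the 12 arrays, counting an array when at least 50% of the probe's spots were. This kept 39582 probes. Over all 49849 probes, before this filter, 194 array values were missing. The number of probes well above background on all 12 arrays was 27989, and 5657 were so on none. Levels are therefore relative to each array's 75th percentile, and a change in total RNA per larva or in most transcripts would not be visible in them.

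Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior degrees of freedom 2.87, residual 9), with a mean per group over all 12 arrays and Benjamini-Hochberg adjustment over the probes kept. The comparisons were each concentration against control, 47.8 against 24.5 mg/L, a moderated F test over the 3 groups and a slope over measured concentration. An adjusted p under 0.05 was called. Where a probe was not well above background on any array of a group, a floored fold is given. It sets the brighter group's mean against the mean, over arrays, of a floored level in the other group. The floored level is the higher of the probe's own value and the array's lowest signal among probes well above background. That lowest signal is not a detection limit for every probe, so the floored fold is not a strict minimum. Array measures were compared by exact two-sided permutation of the control and exposed labels. Unchanged groups were simulated against the same controls for the correlation and the overlap between concentrations, with each probe drawn independently of the others. Figures were drawn with matplotlib 3.10.9.

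The procedure was tested on simulated data for the comparison of 47.8 mg/L with control over 39458 probes. With equal spread in all groups it recovered 27% of 2-fold and 62% of 4-fold changes, with 4 false calls among 39258 unchanged probes. With each group's own spread, which is larger in the controls, it recovered 35% and 69%, with 76 false calls.

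The files do not pair probe names with genes, and 0 of 49849 probe names matched the 64593 genes of the RefSeq table for fPimPro1.hap1.1. The 33 gene lists fixed before the data were examined and the rule for named genes could therefore not be applied. That rule took genes with the largest rise and fall among those past the threshold whose 4 exposed arrays lay all above or all below the 4 controls. Its size criterion was applied to probes in 47.8 mg/L against control, limited to 2 that rose and 2 that fell. SINGLET_39359 was named after its values were seen, as the only probe called between the exposed groups. The tests, comparisons and most alternatives were fixed before the data were examined. Alternatives covered scaling (quantile, array median, percentile of kept probes), normexp background correction with an offset of 50, the authors' deposited table, filters, slide, scan date and replicate number as blocks, array weights, the variance prior, thresholds and leaving out each array. Normexp was run on the median spot signal, in place of the planned mean spot signal, which is not used here. Scan day separated only 24.5 mg/L replicate 4 from the other arrays.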

Results

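Whole-larva gene expression was measured in fathead minnow (Pimephales promelas), a small freshwater fish widely used in toxicity testing, after a 48 h static exposure to IMX-104. IMX-104 is an insensitive munition formulation that contains 2,4-dinitroanisole, nitrotriazolone and RDX. Control water and measured concentrations of 24.5 and 47.8 mg/L were compared, with 4 replicate beakers each. Each beaker held 10 larvae, and RNA from 4 of them was hybridised to 1 one-colour oligonucleotide array. The higher concentrations of the series, 97.3 and 194.5 mg/L, are not analysed here. The 12 arrays carried 49849 probes, named only as CONTIG, SINGLET, UF_Ppr_AF or UF_Ppr_AM followed by a number. The sources used here do not pair these names with genes, so the changes are described by probe, by probe family and by brightness. The 75th percentile of probe intensity ranged from 318.6 on control replicate 4 to 983.5 on 24.5 mg/L replicate 1. Between 65.6% and 83.3% of probes were well above background per array, and 39582 probes entered the tests. The number of arrays limits the precision of every comparison.

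The control arrays lay farther from each other on average than the exposed arrays did. With 1 array per beaker, differences between beakers cannot be told from differences between their arrays. The root-mean-square deviation of an array from the mean of its group's other replicates averaged 0.85 ± 0.30 log2 in controls (SD, n = 4). It averaged 0.53 ± 0.05 at 24.5 mg/L and 0.46 ± 0.01 at 47.8 mg/L (SD, n = 4 each). The values of a group share its replicates, so they were not tested. Control replicates 3 and 4 were at 1.06 and 1.14, while control replicates 1 and 2, at 0.595 and 0.583, were close to the highest exposed value of 0.582. Correlations between arrays, computed across probes, which are not independent, were 0.970 to 0.983 among exposed arrays. They were 0.850 to 0.963 among control arrays and 0.843 to 0.976 between control and exposed arrays. The first principal component carried 50.2% of the variance, and control replicate 4 lay at 237.2 on it, against -71.4 to 111.8 for the other 11 arrays. Sample signal relative to the spike-in RNA was -3.01 ± 0.79 log2 in controls, with control replicate 4 at -4.18, -2.42 ± 0.28 at 24.5 mg/L and -2.34 ± 0.08 at 47.8 mg/L (SD, n = 4 each). The controls differed from the exposed arrays by -0.63 log2 in that measure (exact two-sided permutation test over 495 assignments, p = 0.0182, n = 4 and 8), which did not pass the threshold after adjustment over 6 array measures (Benjamini-Hochberg p = 0.0545). Without control replicate 4 the difference was -0.24 log2 (exact two-sided permutation test over 165 assignments, p = 0.0970, n = 3 and 8). Of the 6 measures, only the first principal component passed, averaging 89.5 in controls and -44.8 in exposed arrays (exact permutation p = 0.00808, Benjamini-Hochberg p = 0.0485). Without control replicate 4 the control mean on it was 40.3 and the component no longer passed (exact permutation p = 0.0242, Benjamini-Hochberg p = 0.0909), and control replicate 3, at -36.2, lay within the exposed range of -71.4 to -21.0. On the second component, with 13.3% of the variance, control replicate 3 lay at -120, against -55.1 to 47.6 for the other 11 arrays. The median SD between spots of the probes with 10 spots averaged 0.227 log2 in controls, with control replicates 2 and 3 at 0.284 and 0.340, and 0.135 in exposed arrays (exact permutation p = 0.0384, Benjamini-Hochberg p = 0.0576; 0.0303 and 0.0909 without control replicate 4). The 75th percentile, the share of probes well above background and the spike-in level had Benjamini-Hochberg p of 0.0566, 0.136 and 0.626 in the same exact permutation test.

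**Figure D1:**
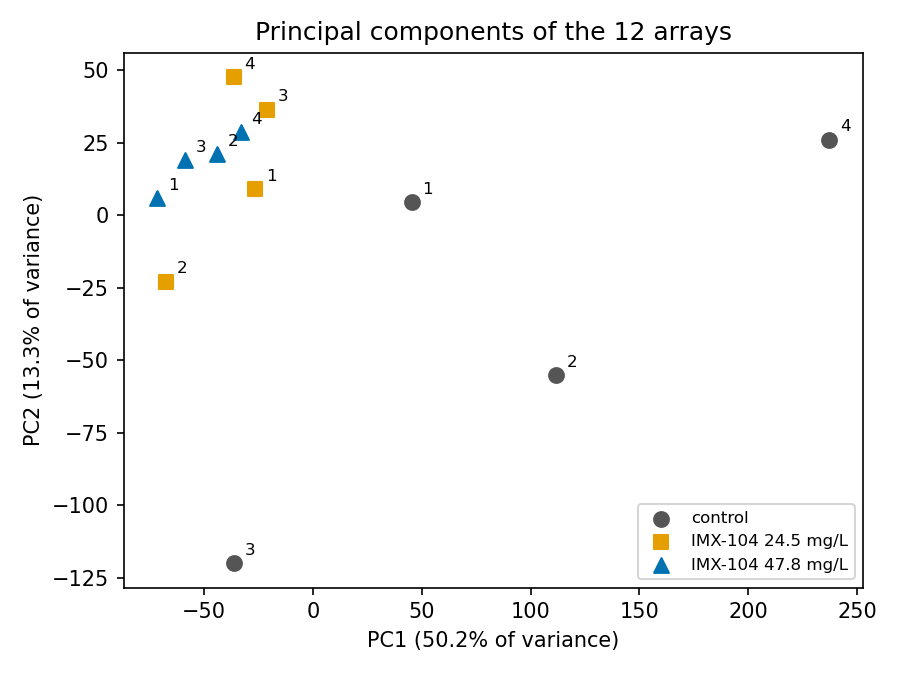
First principal component (x axis, 50.2% of variance) against the second (y axis, 13.3%) for the 12 arrays, with replicate numbers beside the points. The 8 exposed arrays lie close together, while the 4 control arrays spread from -36.2 to 237.2 on the first component. Control replicate 3 lies at -120 on the second.

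**Figure D2:**
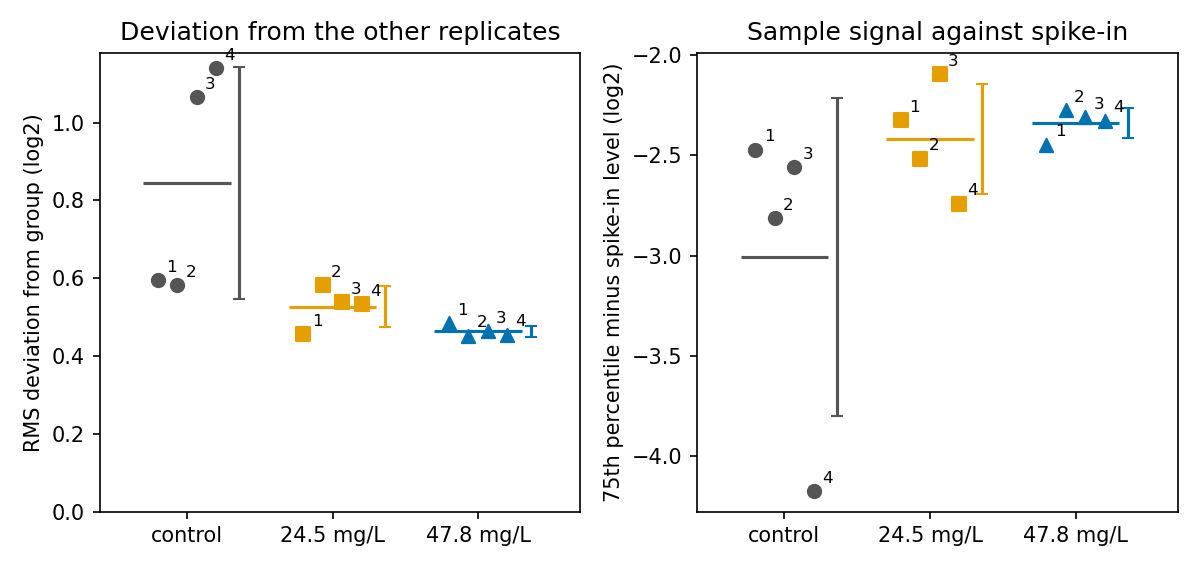
Left, root-mean-square deviation of each array from the mean of its group's other replicates (log2); right, the array's 75th percentile minus its spike-in level (log2). Points are arrays with their replicate numbers, lines are group means and bars are 1 SD; control replicate 4 is at 1.14 on the left and -4.18 on the right.

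The comparison of 47.8 mg/L with control asked which transcripts differed after exposure to the higher of the analysed concentrations. Probe SINGLET_5991 rose: it was not well above background in any of the 4 controls and was well above it in all 4 exposed arrays. Its floored fold was 46.9 (fitted log2 fold change 6.44 ± 0.27 SE, limma adjusted p = 7.44e-07, n = 4 per group). Probe CONTIG5615 rose 75.7-fold (6.24 ± 0.36 SE, limma adjusted p = 8.11e-06, n = 4 per group) and was well above background in 3 of 4 controls. Probe SINGLET_6325 fell from -2.08 ± 1.99 to -6.87 ± 0.40 log2 (SD, n = 4 each, relative to the 75th percentile). It was not well above background on any exposed array and was well above it in 3 of 4 controls, all except control replicate 3. Its floored fall was 16.5-fold, with control replicate 3 entered at its own value (fitted log2 change -4.78 ± 0.74 SE, limma adjusted p = 0.00628). Probe SINGLET_44910 fell by 5.04 ± 1.43 (SE) on the log2 scale with limma adjusted p = 0.0470, close to the threshold, and 47.8 mg/L replicate 3, at 2.99, stayed near the control mean of 3.51 ± 0.33 (SD, n = 4). Its call was lost under 23 of 35 alternative settings (adjusted p over all of them from 0.0177 to 0.205), among them leaving out 24.5 mg/L replicate 1, 2 or 4, 47.8 mg/L replicate 1, 2 or 4, or control replicate 1, 2 or 4 (adjusted p = 0.0538, 0.0571, 0.0621, 0.116, 0.106, 0.102, 0.0604, 0.0976 and 0.0868). In these fits without 1 array its log2 change was -5.15 to -4.43, and over all alternatives it was -8.27 to -3.29. Of its 34 alternatives, SINGLET_6325 lost the call only with slide as a fixed block (adjusted p = 0.211, lowest 0.000101), where its log2 change was -5.10. Its log2 change ranged from -5.69 without control replicate 3 to -1.76 with normexp background correction and quantile normalization. Over the alternatives the log2 fold change of SINGLET_5991 ranged from 2.88, with normexp background correction, whose offset compresses dim signals, to 7.10, and that of CONTIG5615 from 5.03 to 6.95.

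In total 3985 of 39582 probes (10.1%) passed an adjusted p of 0.05 at 47.8 mg/L, 1784 higher and 2201 lower. Their median change was 1.26 log2 in size, with 2872 probes changed at least 2-fold and 453 at least 4-fold. The 4 exposed and 4 control levels did not overlap for 7819 probes (19.8%, against 2.86% by chance), among them 3672 of the 3985. By probe family, 10.72% of singlet-derived, 9.06% of contig-derived and 9.65% of UF_Ppr_AF probes passed the test, shares that were not tested against each other. Of the singlet-derived probes called, 845 were higher and 1275 lower, a balance that turned to 1064 higher and 946 lower after quantile normalization and to 498 higher and 33 lower after scaling to the spike-in RNA. Of the contig-derived probes called, 335 were higher and 317 lower, against 424 and 720 after normexp with the 75th percentile and 188 and 3 after scaling to the spike-in RNA. In the dimmest of 5 equal brightness classes 203 probes were higher and 478 lower, with a median over the class of -0.47 log2. This balance of calls also turned after quantile normalization (411 higher, 248 lower, class median -0.11 log2) and after scaling to the spike-in RNA (183 higher, 19 lower). It did not turn with the array median (252 higher, 495 lower), the percentile of kept probes (201 and 398) or normexp with quantile normalization (204 and 212) or the 75th percentile (1 and 933). In the brightest class 380 were higher and 303 lower, with a median of -0.01. There 612 were higher and 675 lower after normexp and quantile normalization, and 210 and 0 after scaling to the spike-in RNA. The share of higher calls depended on the scaling, being 44.8% with the 75th percentile, 57.2% after quantile normalization, 29.9% after normexp background correction with the 75th percentile and 95.9% after scaling to the spike-in RNA, which called 1051 probes. Without control replicate 4, scaling to the spike-in RNA called 1788 probes, 88.0% of them higher. The median of all tested probes was -0.13 log2, -0.02, -0.24 and 0.54 under those scalings, and 0.17 with spike-in scaling without control replicate 4, so directions are relative to the scaling.

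The same comparison at 24.5 mg/L showed a rise of the same leading probes. SINGLET_5991 had a floored fold of 25.4 over controls (fitted log2 fold change 5.55 ± 0.27 SE, limma adjusted p = 5.13e-06, n = 4 per group). Again it was well above background in 4 of 4 exposed and 0 of 4 control arrays. With slide as a fixed block its adjusted p was 0.0819, the highest of its alternatives (lowest 1.24e-07), and its log2 change was 5.71. CONTIG5615 was 60.4-fold higher (5.92 ± 0.36 SE, limma adjusted p = 1.50e-05, n = 4 per group), and it passed the threshold at both concentrations under all 34 alternative settings. Over the alternatives at 24.5 mg/L, the log2 fold change of SINGLET_5991 ranged from 2.145, with normexp background correction, to 6.14, and that of CONTIG5615 from 4.54 to 6.92. Neither of the probes named for their fall passed the threshold at 24.5 mg/L: SINGLET_6325 changed by -2.88 ± 0.74 (SE, limma adjusted p = 0.0545), and SINGLET_44910 by -2.63 ± 1.43 (SE, limma adjusted p = 0.228). SINGLET_6325 passed it under 8 of 34 alternatives (adjusted p over all of them from 0.00174 to 0.178), with the lowest p without control replicate 3, where its log2 change was -3.79. Control replicate 3, at -4.80 for SINGLET_6325, lay within the range of the 24.5 mg/L arrays.

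At 24.5 mg/L 1094 probes (2.76%) passed the test, 685 higher and 409 lower, with a median change of 1.35 log2 in size. Of these, 902 changed at least 2-fold and 125 at least 4-fold. The groups did not overlap for 5568 probes (14.1%, against 2.86% by chance), among them 1071 of the 1094. Over all 49849 probes, 245 were well above background on all 4 arrays at 24.5 mg/L and on none of the controls, against 4 the other way round; at 47.8 mg/L these counts were 112 and 21. The share of all probes well above background also differed by group, at 78.6% ± 4.61 at 24.5 mg/L, 73.3% ± 3.76 at 47.8 mg/L and 70.34% ± 5.89 in controls (SD, n = 4 each). The share of higher calls was 62.6% with the 75th percentile, 46.7% after normexp and quantile normalization, 24.1% after normexp with the 75th percentile and 98.5% of the 135 calls after scaling to the spike-in RNA. Without control replicate 4, spike-in scaling gave 338 calls, 96.7% of them higher.

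**Figure D3:**
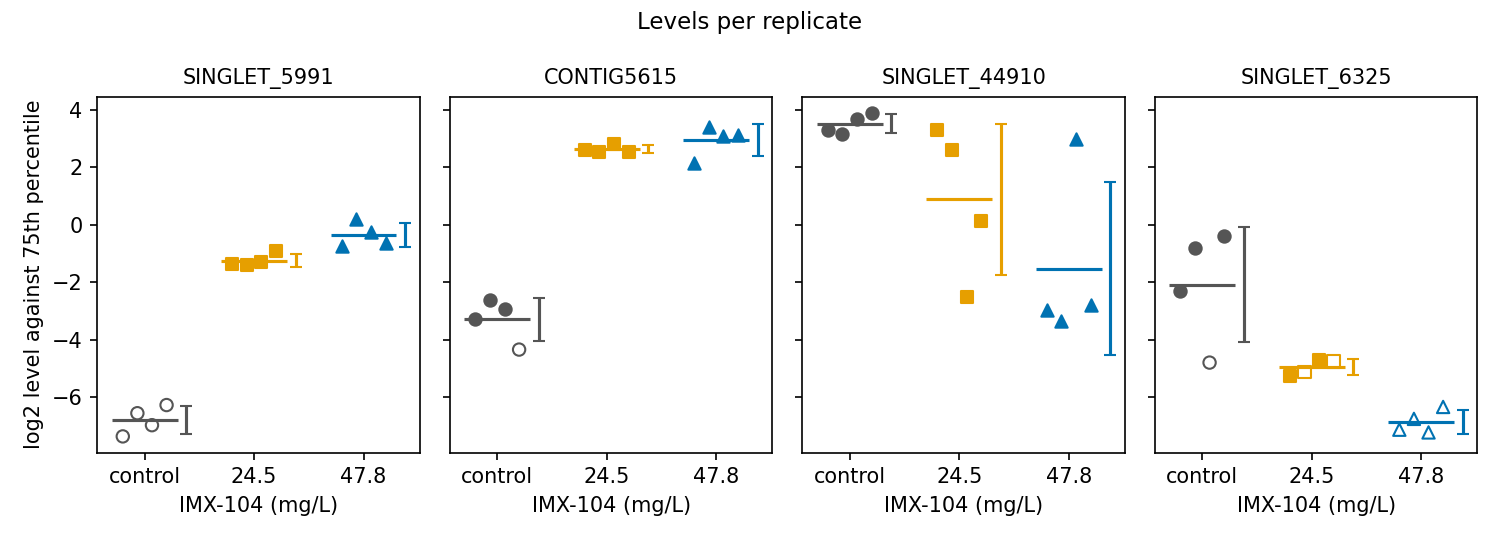
Log2 level relative to the array's 75th percentile (y axis) of the 4 named probes in each replicate of each concentration of IMX-104 (x axis, mg/L). Filled points were well above background and open points were not; lines are group means and bars are 1 SD (n = 4). SINGLET_5991 and CONTIG5615 lie higher on all 8 exposed arrays than on any control array.

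With a weight for each group's spread, 63 probes were called at 24.5 mg/L and 1899 at 47.8 mg/L. The number of calls also changed when single arrays were left out. At 24.5 mg/L, leaving out control replicate 1, 2, 3 or 4 gave 3024, 69, 11626 and 587 probes, leaving out 24.5 mg/L replicate 1, 2, 3 or 4 gave 135, 69, 53 and 38, and leaving out 47.8 mg/L replicate 1, 2, 3 or 4, which share the spread estimate, gave 220, 220, 218 and 178. At 47.8 mg/L, the counts without those control replicates were 4874, 1097, 13942 and 2630. They were 2502, 2656, 2707 and 2753 without the 24.5 mg/L replicates and 1056, 1128, 748 and 1312 without the 47.8 mg/L replicates, in the same order. The balance of directions moved as well: without control replicate 3 the calls at 24.5 mg/L were 4711 higher and 6915 lower. At 47.8 mg/L higher calls became the majority in 5 of the 12 fits, those without control replicate 1, 2 or 4 (2442 higher and 2432 lower, 568 and 529, 1364 and 1266) and without 47.8 mg/L replicate 1 or 3 (576 and 480, 425 and 323). Every called probe of either comparison kept its direction in all 12 fits, which was largely fixed in advance. The groups did not overlap for 1071 of the 1094 probes called at 24.5 mg/L and 3672 of the 3985 at 47.8 mg/L. Leaving out 1 array could not turn the direction of those. Leaving out an array of the group not compared leaves a change as it was. In every fit, 34 probes at 24.5 mg/L (30 higher, 4 lower) and 645 at 47.8 mg/L (382 higher, 263 lower) were called. These 645 had a median change of 1.70 log2 in size, and 621 changed at least 2-fold. Both concentrations shared 33 such probes with the same direction, 29 of them higher.

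Slides held the groups unevenly. Control and exposed arrays shared only slide 1 (control replicate 4 with 24.5 mg/L replicate 3) and slide 3 (control replicate 1 with 47.8 mg/L replicate 2), and slide 4 held only control replicates 2 and 3. With slide as a fixed block, limma called 1 probe at 24.5 mg/L and 5 at 47.8 mg/L, while 9774 and 7701 probes had an unadjusted p under 0.05. All probes called without the block kept their direction. The block links exposed to control arrays only through slides 1 and 3, whose arrays were also in the fit that made the calls. Their median change at 47.8 mg/L was 1.26 log2 in size without the block and 1.27 with it, while the median SE rose from 0.29 to 0.41 and the residual degrees of freedom fell from 9 to 4. At 24.5 mg/L the median change was 1.35 and 1.43 log2, and the SE rose from 0.27 to 0.39. Within slide 3, 1669 of the 1840 probes called at 47.8 mg/L without that slide's pair (90.7%) differed in the called direction, against 72.6% of all probes, by a median of 0.72 log2 against 1.56 in the fit without the pair. Within slide 1, 86 of 86 probes called at 24.5 mg/L without its pair did so, against 73.4% of all probes, by a median of 2.69 log2 against 1.83. With slide as a random block, 1463 and 3442 probes were called at 24.5 and 47.8 mg/L.

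Between the exposed groups, few differences were detectable. Only SINGLET_39359 passed the threshold for 47.8 against 24.5 mg/L: its level was -4.24 ± 0.38 log2 at 47.8 mg/L, -6.51 ± 0.17 at 24.5 mg/L and -6.77 ± 0.35 in controls (SD, n = 4 each). It was well above background on 4 of 4 arrays at 47.8 mg/L and on 0 of 4 in each other group. Its floored fold was 4.01 over 24.5 mg/L (fitted difference 2.27 ± 0.23 log2, SE, limma adjusted p = 0.0205) and 3.18 over controls (limma adjusted p = 0.000359). The call was lost under 18 of 34 alternative settings (adjusted p from 0.00199 to 1). The difference was 0.62 and 0.71 log2 under the 2 normexp settings and 2.08 to 2.46 under the other 32, of which 16 lost the call. Among these 16 were leaving out 24.5 mg/L replicate 1, 2, 3 or 4, 47.8 mg/L replicate 1 or 2, or control replicate 2 (adjusted p = 0.115, 0.156, 0.159, 0.1002, 0.0729, 0.0920 and 0.0640). With limma 1498 probes had an unadjusted p under 0.05, fewer than chance alone would give. The median half-width of the unadjusted 95% interval of a difference was 0.64 log2, and a call after adjustment needs a larger difference than that. The fit pools the spread with the controls, whose probe SD averaged 0.637 log2, against 0.363 at 24.5 mg/L and 0.310 at 47.8 mg/L. Fitting only the exposed groups gave 3516 such probes and 0 calls. With a weight for each group's spread there were 3745 such probes and 1 call. Groups did not overlap for 2064 probes (5.21%, against 2.86% by chance). SINGLET_5991 differed between the concentrations by 0.89 ± 0.27 log2 and CONTIG5615 by 0.33 ± 0.36 (SE, limma adjusted p = 1 for both). Over all 49849 probes, 90 were well above background on all 4 arrays at 24.5 mg/L and on none at 47.8 mg/L, against 1 the other way round, beside array-wide shares of 78.6% and 73.3%.

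Over the dose series, 1762 probes differed among the 3 groups (limma moderated F test, adjusted p under 0.05), and 2960 had a linear trend over the measured concentrations, 1324 rising and 1636 falling. With slide as a fixed block these counts were 1 and 0, with an unadjusted p under 0.05 for 5848 and 3479 probes. Without control replicate 3 they were 11103 and 9877, and without control replicate 2 they were 320 and 605.

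The changes at both concentrations were compared to see how far they coincided. Of the probes called, 957 were called at both concentrations in the same direction, 591 higher and 366 lower, and 0 in opposite directions. Independent lists of those sizes would share 30.9 higher and 22.7 lower, a value that leaves out the shared controls. The count of 957 became 38 to 9860 when 1 array was left out, and 1 with slide as a fixed block. Of the 3985 probes called at 47.8 mg/L, 99.6% had the same direction at 24.5 mg/L. In 100 simulations of unchanged groups against the same controls, the 1094 and 3985 probes of lowest p shared 815 to 890 in the same direction and 0 to 4 in opposite directions, and 95.5% to 96.7% of the 3985 had the same direction at 24.5 mg/L. With the measured arrays and the controls split so that each concentration had its own pair, lists of those sizes shared 225 to 596 probes in the same direction and 0 to 8 in opposite directions over 6 splits, and 80.9% to 95.7% of the 3985 had the same direction. Across probes, which are not independent, log2 fold changes correlated at r = 0.893 with a covariance of 0.507. Unchanged groups simulated in the same way gave r = 0.759 on average (0.750 to 0.772) and a covariance of 0.146, so the covariances differed by 0.361. The simulations drew each probe independently. Correlation between probes could widen the simulated ranges, so they do not exclude chance. With the controls split, r was 0.430 to 0.742 and the covariance 0.280 to 0.457 over 6 splits. Signs matched for 86.9% of probes with shared controls, 76.6% in the simulations and 67.6% to 79.2% with split controls. Probes called at only 1 concentration, 137 at 24.5 mg/L and 3028 at 47.8 mg/L, are not thereby shown to differ between them.

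**Figure D4:**
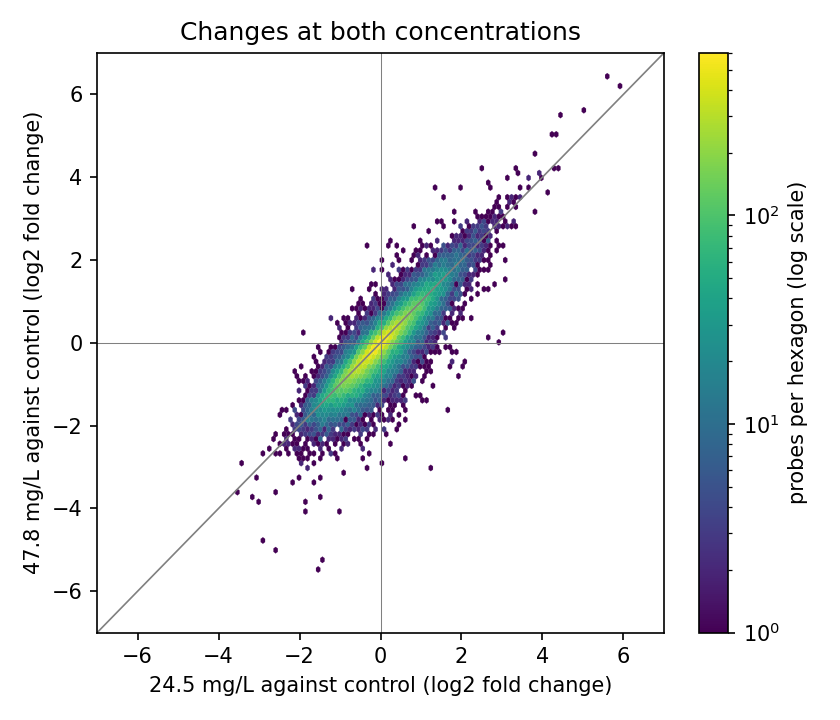
Log2 fold change against control at 24.5 mg/L (x axis) and at 47.8 mg/L (y axis) for the tested probes, with colour showing the number of probes per hexagon on a log scale. The diagonal marks equal change. Across probes r was 0.893 with a covariance of 0.507. Simulations without any effect, with probes drawn independently, gave an r of 0.759 and a covariance of 0.146 through the shared controls.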

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

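The shares within slides and the counts over other splits of the arrays were tests fixed before their results were seen, and the orders of the exposed arrays were chosen after. Among the 39 groups of 4 arrays examined for a value far from the others, 1 was found, and chance marks about 1 in 20 such groups. It was the level of SINGLET_44910 on 47.8 mg/L replicate 3, at 2.99 log2 relative to the 75th percentile, against -3.35 to -2.79 on the other 3 arrays of that group. At 24.5 mg/L the same probe ranged from -2.50 to 3.29.

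Other splits of the arrays bear on each count. For 24.5 mg/L against control, 1 of the 35 splits of the 8 arrays, the real one, gave as many as 1094 probes, and the highest other gave 1. For 47.8 mg/L against control it was also 1 of 35, with 3985 probes against 2. This is the smallest share that 35 splits can give, so it makes chance assignment unlikely for both counts without excluding it. For 47.8 against 24.5 mg/L, 2 of 35 splits gave at least the 1 probe called, the highest other giving 2, so chance is not excluded there. Over 100 random splits into 3 groups, the real one included, 1 gave as many as 1762 probes in the F test (highest other 1483). For the dose trend, 2 gave as many as 2960, the highest other giving 3525. Chance assignment is thus unlikely for both counts. The only other draws with over 5 probes in either test were 2 that kept the 4 controls together and exchanged 1 array between the exposed groups (1189 and 1483 in the F test, 2664 and 3525 for the trend), of which 1 reached 2960. When the controls were kept and the 8 exposed arrays were put in all 70 orders, 6 orders, the real one included, gave as many as 2960 probes with a trend, the highest giving 3762 and the median 6. A difference between control and exposed arrays with no order of the concentrations is therefore not excluded for the trend count. In the F test, which takes no account of order, 2 of the 70 gave as many as 1762 probes, the real order and the one with the exposed groups exchanged.

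A technical question for the calls is whether differences between slides produced them, since the slides held the groups unevenly. If they had, probes called without a slide's own pair of control and exposed arrays would differ in either direction within that slide. In the lower of the pairs 90.7% went in the called direction, against 72.6% of all probes (slide 3). In the other 86 of 86 probes did, against 73.4% (slide 1, with control replicate 4). Control replicates 2 and 3, both unexposed and on slide 4, also differed along the direction that parted exposed from control arrays (r = -0.628). Differences between beakers or between their arrays could thus give such shares, and 1 pair per slide cannot decide whether slide differences produced the calls. The median change within the slide was 0.72 log2 against 1.56 in the fit without the pair on slide 3, and 2.69 against 1.83 on slide 1, each from 1 pair of arrays, so a contribution of the slides stays open. With slide as a fixed block the called probes all kept their direction, and their median change was 1.43 log2 in size at 24.5 mg/L and 1.27 at 47.8 mg/L, against 1.35 and 1.26 without it. That fit links exposed to control arrays only through the same pairs on slides 1 and 3. These arrays were also in the fit that made the calls, so the block adds no independent support. Calls fell to 1 and 5 as the median SE rose from 0.27 to 0.39 and from 0.29 to 0.41 and the residual degrees of freedom fell from 9 to 4. Without the slide that held only controls, a fit chosen after seeing the data, 7850 and 11332 probes were called against control replicates 1 and 4. Calls thus did not need that slide. Its contribution to the calls of the full fit stays open, since no exposed array shared it. Exposure to IMX-104, the comparison fixed before the data were examined, remains a candidate explanation that was not separated here from slide differences.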

How the results depend on the processing

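The fits without the slide of controls only, with a weight for each group's spread and with spike-in scaling, with or without control replicate 4, were chosen after seeing the data; the other settings were fixed before. Values are the probes called at 24.5 mg/L, at 47.8 mg/L, at 47.8 against 24.5 mg/L, in the F test and for the trend, then those called at both concentrations in the same direction, where they moved by over 1.5 times from 1094, 3985, 1, 1762, 2960 and 957. No named probe and no correlation changed sign, but the balance of higher to lower calls turned with scaling, arrays and other settings. From 62.6% higher at 24.5 mg/L and 44.8% at 47.8 mg/L, the majority turned in 2 and 4 of 7 other scalings (24.1% to 98.5% and 29.9% to 95.9% higher), in 1 and 5 of 12 fits without 1 array (40.5% to 85.5% and 35.5% to 56.8%) and in 3 and 4 of 16 other settings (41.9% to 100% and 36.6% to 100%, the last being the fixed slide block's 1 and 5 calls). Over named probes, comparisons and settings, the side of the threshold was kept 257 times, lost 43 times and gained 8 times. The cause was not tested except where named.

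Leaving out 1 array at a time gave 38 to 11626, 748 to 13942, 0 to 2, 320 to 11103, 605 to 9877 and 38 to 9860, with the highest counts without control replicate 3 except for 47.8 against 24.5 mg/L; r between concentrations ranged from 0.843 to 0.927. Quantile normalization gave 1663 at 24.5 mg/L. Normexp with quantile normalization gave 4216 at 24.5 mg/L, 0 between concentrations, 3792 in the F test and 3143 at both; normexp with the 75th percentile gave 7100, 6731, 0, 4993 in the F test and 4642 at both. No filter on dim probes gave 512 at 24.5 mg/L and 469 at both. Only probes well above background on all arrays, fewer probes, gave 1821 at 24.5 mg/L, 0 between concentrations and 1512 at both. Slide as a random block (consensus correlation 0.118) gave a trend in 1937, and as a fixed block 1, 5, 0, 1, 0 and 1, with fewer residual degrees of freedom. Scan date as a block, which leaves out 24.5 mg/L replicate 4, gave 38 at 24.5 mg/L, 0 between concentrations, 636 in the F test and 38 at both. Array weights gave 11343, 14862, 13244 in the F test, 9983 for the trend and 9872 at both. A trended robust prior gave 1777 at 24.5 mg/L, 0 between concentrations and 1484 at both. Without moderation the counts were 185, 2467, 0, 841, 1654 and 176, and at an adjusted p under 0.01 they were 33, 374, 0, 152, 225 and 32. Fitting only the groups compared gave 38, 505 and 0. Without the slide of controls only, they were 7850, 11332, 0, 5183, 1440 and 6778. A weight for each group's spread gave 63, 1899, 919 in the F test, 432 for the trend and 62 at both. Spike-in scaling gave 135, 1051, 0, 468, 450 and 127, and without control replicate 4 it gave 338, 1788, 710 in the F test, 1034 for the trend, 309 at both and r = 0.843. With split controls r was 0.725, 0.475, 0.541, 0.498, 0.430 and 0.742.

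With replicate number as a block the counts were 61, 2393, 0, 592, 1447 and 60. The numbers did not pair the beakers: same-numbered arrays correlated at -0.208 to 0.234 in their deviations from the group means, 2 of 12 pairs exceeded 0.1, and 2 of 12 arrays correlated best with their own number. The tests of gene lists and the mean over a gene's probes were not run, because probe names matched no gene. Signal over background limits the dimmest probes, for which only a floored fold is given near background.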

Other observations

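The tests of spike-in level and of sample signal against spike-in below were chosen after those values were seen; the spot-noise, brightness and 3-control tests were fixed before their own results were seen, but after both patterns and the correlations between control differences had been noticed. The test of slide 4 and the brightness and quantile values for the other pairs were chosen after the correlations were seen. Control replicate 4 stood apart from the other 11 arrays. A dim scan or weak hybridisation would have lowered its spike-in signal, but this was 0.46 log2 above the median of the others. Noise of single spots would shrink on probes averaged over 10 spots to a ratio near 0.316, yet the deviation on 10-spot probes was 0.861 of that on single-spot probes of like brightness (0.635 to 0.833 on the other 11 arrays). Its 75th percentile relative to spike-in lay -1.73 log2 from the median of the others, so less labelled sample RNA for the same spike-in RNA is a candidate explanation; whether sample input, spike-in input or the larvae differed stays open. No biological explanation was tested, since the labels give none for a single beaker.

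The control arrays also differed from each other along the direction that parted exposed from control arrays. Across probes, which are not independent, the difference of 2 controls was correlated with the exposed mean minus the other 2, a comparison without shared arrays. For replicates 1 minus 2, 1 minus 3, 1 minus 4, 2 minus 3, 2 minus 4 and 3 minus 4, r was 0.442, -0.344, 0.412, -0.628, 0.0860 and 0.581, and after quantile normalization 0.4501, -0.310, 0.427, -0.611, 0.1004 and 0.572. A distortion that depends on brightness was predicted to leave no correlation within 5 brightness classes, but for 3 minus 4, the pair tested, the lowest of the 5 was 0.512. The classes are wide, the brightest spanning 1.15 to 8.43 log2, so such a distortion could still vary within them. The narrowest class, from -3.89 to -2.51 log2, gave r = 0.613, which argues against brightness as the whole cause. Over the classes r ranged from 0.312 to 0.540, -0.375 to -0.171, 0.321 to 0.460 and -0.645 to -0.534 for the first 4 pairs, and only from 0.0477 to 0.117 for 2 minus 4. Control replicate 4 alone does not account for it either: without that array, control replicate 2 minus 3 correlated at r = -0.428 with the exposed mean minus control replicate 1, the largest in size of 3 such tests, the others being 0.227 and -0.168. An effect common to slide 4, which held control replicates 2 and 3, would cancel in 2 minus 3, yet that pair gave r = -0.628, the largest in size of the 6, so it is not the whole cause. A candidate reading is that part of the exposed-control difference lies on an axis along which unexposed beakers, or their arrays, vary as well. No biological explanation was tested.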
